A study of Drosophila melanogaster with 36 samples.

How the data were processed

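Whole wild-type flies of both sexes were compared between exposure to CMIT/MIT aerosol and filtered air on days 1, 2 and 7, with 3 libraries in each of 12 groups. Total RNA was taken with Trizol and made into 3' end libraries, per the labels' protocols. The deposited values are raw read counts per gene, with no normalization, per the submitters' processing notes: reads were trimmed with fastp, aligned to dm6 with STAR and counted with HTSeq. Versions of those tools, the annotation release and the strand setting used in counting are not given in the sources used here. All 36 files had the same 17583 entries, 17582 of them with a gene symbol and 1 blank, and the blank entry held at most 0.000107% of a library. Identifiers and coordinates were matched by symbol to the BDGP6.54 annotation, which covered 17536 symbols. Mitochondrially encoded genes were matched through RefSeq synonyms.

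Depth ranged from 4681333 to 17182966 counts per library. Genes with at least 1 count numbered 13173 to 14456 in male and 10237 to 13199 in female libraries. The mitochondrial large ribosomal RNA took 3.10% to 15.2% of counts in males and 3.13% to 16.8% in females. Between replicates that are not mixed libraries, correlations of log2 CPM ranged from 0.948 to 0.991 over 32 pairs. Chi-square per degree of freedom in those pairs was at least 10.4, with a median of 50.7, so no pair was a repeat of 1 library. The labels give no sequencing batch.

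Each sex was fitted apart with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 and a minimum total of 15, TMM scaling, and the quasi-likelihood F test of exposed minus air libraries per day over 18 libraries in 6 groups. Positive log2 fold changes mean higher in exposed flies, with a prior count of 0.125. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Change over days was tested as any difference among the 3 daily effects within a sex. Sex differences were tested as the effect in females minus that in males in a fit of all 36 libraries. Means and SDs of named genes are CPM with TMM scaling within each sex, list sums are CPM with TMM scaling over all 36 libraries, and sex markers and floors are CPM of the library total. Counting intervals are of pooled counts against library totals. Tested on simulated data of the same design, 4-fold changes were recovered at 33.3%, 36.4% and 50% in males and at 57.6%, 74.2% and 78.8% in females on days 1, 2 and 7. For 2-fold changes recovery was at most 2.99% in males and at most 40.3% in females. The test of change over days recovered 0% of 4-fold changes in males and 50% in females, and that of sex difference 19.7%, 9.09% and 13.6% on days 1, 2 and 7.

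Gene lists, 37 in all, covered detoxification, stress, immunity, metabolism and tissue markers, and were fixed before the data were examined, as were the comparisons, the thresholds, the rule for named genes and most alternatives. Each list with at least 3 tested genes was tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Gene lists were also tested by adjusting over the list alone. Setting genes at 0 in 1 arm to their bound moved 7 of 222 list medians, by at most 0.12. Named genes were, per comparison, up to 8 in each direction past the threshold with the largest fold change, no overlap between arms and a mean of at least 5 CPM in the higher arm. Up to 4 members with the smallest p were named from each list with a member past the threshold, and where fewer than 5 genes passed in a direction, the 5 with the smallest p. Difference tests named up to 5 genes per direction, or 10 for the days. Some genes of the rule are left out for length, and examples given for other lists were chosen after their values were seen.

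Libraries with more than 100 CPM of roX1 and more than 1000 CPM of Yp1 were called mixed, a rule set after the data were seen, and 2 libraries met it. They were kept, and every comparison was repeated without them. Other alternatives were DESeq2 1.42.0, its size factors, no filter, a filter of 5 CPM in 3 libraries, only the 6 libraries compared, all 36 libraries, the threshold in the series text (over 1.5-fold and unadjusted p below 0.05), and leaving out each library. Replicate numbers were checked and do not pair exposed with air libraries over all days, although some like numbers matched on day 2.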

Results

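Gene expression was measured in whole wild-type flies of both sexes on days 1, 2 and 7 of an inhalation study of CMIT/MIT, a mixture of chloromethylisothiazolinone and methylisothiazolinone used as a biocide. Exposed flies had breathed 330 mg/m3 of it as an aerosol during 1 hour, and control flies had breathed filtered air. The assay was 3' end sequencing of total RNA, which counts reads near the end of each transcript. Sex, day and treatment gave 12 groups of 3 libraries, 36 libraries in all. Library depth ranged from 4681333 to 15444994 counts in males and from 9525565 to 17182966 in females. At these depths 3 counts correspond to 0.641 CPM (the counts-per-million unit) in the shallowest library and 0.175 CPM in the deepest. Intervals and floors of this kind cover counting error only, since PCR copies are not independent molecules. The labels do not say whether replicates came from separate cultures of flies, so every p-value below measures only the spread between samples. Nor do they say whether days count from the exposure. Titles of exposed samples carry T where the column headers carry T2, with no explanation. Coordinates refer to the dm6 (BDGP6) assembly.

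Sex was read from the letters M and F in the library titles and checked against transcripts known to mark each sex. The RNA roX1, part of the male dosage compensation complex, ranged from 847 to 1721 CPM in 17 libraries titled male and from 0.837 to 7.01 CPM in 17 titled female. Yolk protein gene Yp1 ranged from 3248 to 15752 CPM in the same 17 female libraries and from 0.944 to 176 CPM in the 17 male ones. The remaining 2 libraries, replicate 3 of day 2 exposed males and replicate 1 of day 2 exposed females, held markers of both sexes and are called the mixed libraries here. The mixed library titled male had 209.8 CPM of roX1 and 6700 CPM of Yp1, and the one titled female had 254 CPM of roX1 and 6206 CPM of Yp1. The oocyte thioredoxin gene dhd, at most 38.7 CPM in the 17 male libraries, stood at 4129 CPM in the mixed library titled male. Sex peptide SP, at most 3.61 CPM in the 17 female libraries, stood at 598 CPM in the mixed library titled female. Both mixed libraries belong to the exposed arm of day 2, so that day was tested with and without them. They also enter the shared estimate of spread on the other days.

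**Figure D1:**
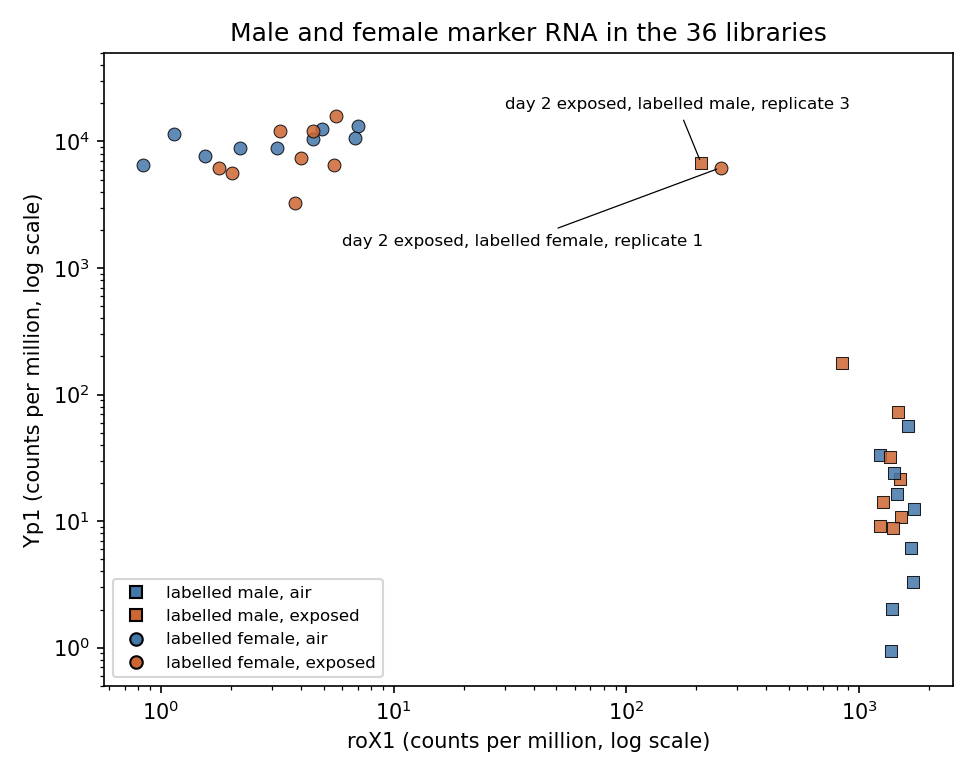
The log-scaled axes give roX1 and Yp1 in CPM for each of the 36 libraries, coloured by treatment. Squares are libraries titled male and circles those titled female. The 2 mixed libraries, at 209.8 and 254 CPM of roX1, lie between the 17 male libraries (847 CPM or more) and the 17 female libraries (7.01 CPM or less).

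The first comparison asked what exposure changed in females on day 1. Of 9893 genes tested, 9 rose and 17 fell (edgeR, adjusted p below 0.05; n = 3 per arm). The largest fold was that of Alp9 (FBgn0035620; 3L, 5595542 to 5597422), an alkaline phosphatase gene. Its mean was 19.1 CPM ± 9.14 (SD) in air and 0.0246 CPM ± 0.0427 in exposed females, a log2 fold change of -9.01 (SE 1.35, adjusted p = 0.0176). The exposed libraries held 1 count of it against 688 in air, a ratio of 768 with a 95% counting interval of 137 to 30394 (exact binomial). CG33306 had -5.03 and Diedel3 -4.39. Fold changes of the predicted serine protease gene CG7542 and the mannosidase gene LManVI were -4.49 and -4.45. The same direction held for CG43055 (-4.01), the cytochrome P450 gene Cyp313a1 (-3.005) and CG15201 (-2.14). CG7631 and CG13325, outside the rule for named genes, had no count in any exposed library, which makes them at least 9.97-fold and at least 6.495-fold lower. Among the genes that rose, the stress-induced nuclease gene Sid (FBgn0039593) had a log2 fold change of 3.19 (SE 0.58, adjusted p = 0.0364). CG16772 rose by 2.31, CG14762 by 1.80, CG32645 by 1.63 and CG5953 by 0.92. The calcium channel gene cac rose by 1.86 (8.50 CPM ± 1.85 to 30.9 CPM ± 4.67), the mitophagy receptor gene BNIP3 by 1.77 and the ankyrin gene Ank2 by 1.27. Arms did not overlap in 16.8% of all genes tested, where chance gives 10% on average. Genes are not independent, and the spread of this share between splits was not tested, so it is a description only.

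By gene list, the 41 midgut digestive enzymes stood out on day 1 in females, with a median log2 fold change of -1.78 (quartiles -2.38 and -0.99). None passed over all genes, whereas 23 fell and 2 rose when adjusted over the list alone. Examples are the trypsin-like protease genes Jon25Bii (-5.95, SE 1.31, adjusted p = 0.05998) and Jon25Bi (-5.77, SE 1.28, adjusted p = 0.05998), neither past the threshold over all genes. Both passed without the mixed libraries of day 2 (adjusted p = 0.0214 and 0.00931). As a set the list fell by the preset correlation of camera (adjusted p = 6.5e-19), a call lost at adjusted p = 0.478 with an estimated correlation. Summed over the list, digestive enzyme transcripts came to 8236 CPM ± 2428 in air and 2863 CPM ± 518 in exposed females. The 32 antimicrobial peptides had a median of 1.06 and rose as a set (adjusted p = 6.9e-05; adjusted p = 0.685 with an estimated correlation), and 8 rose and 2 fell when adjusted over the list alone. CecA2 (4.79, adjusted p = 0.143) and CecA1 (3.82, adjusted p = 0.146) were positive, and Drsl5 (-2.20, adjusted p = 0.0879) negative. Transcripts of neurons had a median of 0.92, with 13 of 14 members positive (adjusted p = 1.6e-07; adjusted p = 0.478 with an estimated correlation). Of these 14, cac rose over all genes and 4 rose when adjusted over the list alone. The GABA receptor gene Rdl had 1.30 (adjusted p = 0.106), and the sodium channel gene para 1.19 (adjusted p = 0.161).

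On day 1 in females 13 further lists passed camera at the preset correlation, 16 in all, and none of the 16 did with an estimated correlation (lowest adjusted p = 0.478). Rising sets were Turandot and JAK-STAT genes (median 0.94), cytosolic ribosomal proteins (0.13) and photoreceptor genes (0.19). Falling sets were UDP-glycosyltransferases (-0.65), odorant binding and taste genes (-0.78), Malpighian tubule genes (-0.55), drug and organic anion transporters (-0.51), and fat body and haemolymph genes (-0.50). The others were mitochondrially encoded genes (-0.43), cytochrome P450s (-0.32), haemocyte genes (-0.30), superoxide and peroxide defence (-0.18) and nuclear oxidative phosphorylation genes (-0.17). Adjusted p with an estimated correlation was 0.478 for the Turandot, UDP-glycosyltransferase, odorant binding, Malpighian tubule, transporter and haemocyte lists. For the remaining 7 it was 0.624 (photoreceptor), 0.685 (fat body, mitochondrially encoded, superoxide), 0.743 (P450s) and 0.796 (ribosomal, oxidative phosphorylation). Metallothionein genes, which encode metal-binding proteins, made up the superoxide list's 3 members that fell when adjusted over the list alone. MtnC had -2.05 (adjusted p = 0.05998), MtnB -3.85 (adjusted p = 0.0829) and MtnD -2.52 (adjusted p = 0.140). Leaving out the mixed libraries, MtnC (adjusted p = 0.0457) and MtnB (0.0327) passed and MtnD (0.142) did not. Of 23 muscle genes, the flight muscle actin gene Act88F fell by 5.32 (SE 1.05, adjusted p = 0.0459), from 1.46 CPM ± 0.875 to 0.0246 CPM ± 0.0427, and none rose over all genes. That rests on 51 counts against 1, a ratio of 57.0 with a 95% counting interval of 9.77 to 2293. Myosin heavy chain gene Mhc had 0.98 (adjusted p = 0.0523, or 0.0457 without the mixed libraries).

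The count of 26 genes rested on single libraries. Without air replicate 1 it was 0, without air replicate 2 it was 2, without air replicate 3 it was 9, without exposed replicate 2 it was 3 and without exposed replicate 3 it was 0. Leaving out the mixed libraries, which belong to day 2, gave 54 genes (16 higher, 38 lower), 26 of them shared. List calls moved from 16 to 10 without air replicate 2 and to 8 without exposed replicate 3. DESeq2 called 273 genes.

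Single libraries also decided list calls in females on day 1, given here by the adjusted p of the list without that library. Air replicate 2 decided oxidative phosphorylation (0.112), photoreceptor (0.0696), fat body (0.0673), haemocyte (0.0673), Malpighian tubule (0.0696) and transporter genes (0.0696). Exposed replicate 3 decided P450s (0.0942), superoxide defence (0.110), mitochondrial (0.285), ribosomal (0.0858), fat body (0.185), haemocyte (0.0560), Malpighian tubule (0.285) and transporter genes (0.103). Air replicate 3 decided Turandot (0.0890), mitochondrial (0.0890) and ribosomal genes (0.176), and air replicate 1 photoreceptor genes (0.0794). Exposed replicate 1 decided superoxide defence (0.0617), oxidative phosphorylation (0.0526) and transporter genes (0.113). Exposed replicate 2 decided Turandot (0.444), oxidative phosphorylation (0.0515) and photoreceptor genes (0.454), and without it the Turandot median was -0.05. The lists of digestive enzymes, antimicrobial peptides, neurons, odorant binding genes and UDP-glycosyltransferases passed without any 1 library of that day.

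The question for females on day 2 was the same. Of 9893 genes, 2 rose and 43 fell. The yellow family gene yellow-g (FBgn0041709; 3L, 2269881 to 2272769), which acts in forming the eggshell, had a mean of 111 CPM ± 59.3 (SD) in air and 0.512 CPM ± 0.497 in exposed females. Its log2 fold change was -7.72 (SE 0.66, adjusted p = 1.2e-05, n = 3 per arm). Its neighbour yellow-g2 fell by 7.46 and CG13114 by 7.16. CG1077 (-6.24), CG15570 (-6.21) and CG10163 (-6.17) also fell, CG1077 by 299 counts against 3, a ratio of 67.5 with a 95% counting interval of 22.9 to 329. A transfer RNA gene, tRNA:Ala-TGC-1-1, had -6.88 (SE 1.28, adjusted p = 0.0170), and missed the threshold without the mixed libraries (-6.33, adjusted p = 0.0527). No exposed library held a count of CG31926, whose air mean of 8.06 CPM makes it at least 26.3-fold lower against a floor of 3 counts per library. The genes that rose were CG14245 (1.61, SE 0.34, adjusted p = 0.0441) and TBC1D5 (0.96, SE 0.20, adjusted p = 0.0410). Arms did not overlap in 12.5% of all genes tested, where chance gives 10% on average, with a spread that was not tested.

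Of 29 ovary and eggshell genes, 9 fell over all genes and none rose. Adjusted over the list alone, 17 fell and 1 rose. The list's median was -1.75 (quartiles -4.65 and 0.12), and its fall held with an estimated correlation (adjusted p = 8.4e-27 at the preset one; adjusted p = 0.0101 with an estimated correlation). Chorion protein genes led it: Cp7Fb went from 302 CPM ± 37.5 to 8.90 CPM ± 8.14 (-5.08, SE 0.57, adjusted p = 0.000126) and Cp18 from 388 CPM ± 36.7 to 9.33 CPM ± 10.7 (-5.38). Summed over the list, transcripts came to 21119.5 CPM ± 929 in air and 6050.2 CPM ± 2575 in exposed females. The yolk protein genes, which encode the main egg nutrients, fell as a set (median -1.72, adjusted p = 5.2e-10; adjusted p = 0.0286 with an estimated correlation). Yp2 went from 8771 CPM ± 2799 to 2305 CPM ± 1169.6 (-1.93, SE 0.33, adjusted p = 0.00807), Yp3 had -1.72 (adjusted p = 0.0194) and Yp1 -1.33 (adjusted p = 0.0910). All 3 fell when adjusted over the list alone. Of the 3 exposed libraries 1 is mixed. The ovary and eggshell list had, with both mixed libraries left out, a median of -2.58, 19 members lower and 1 higher over the list alone, and adjusted p = 0.0313 with an estimated correlation. With both left out, Yp3 kept its fold and missed the threshold (-1.72, adjusted p = 0.0527), and the yolk list had adjusted p = 0.0587 with an estimated correlation.

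**Figure D2:**
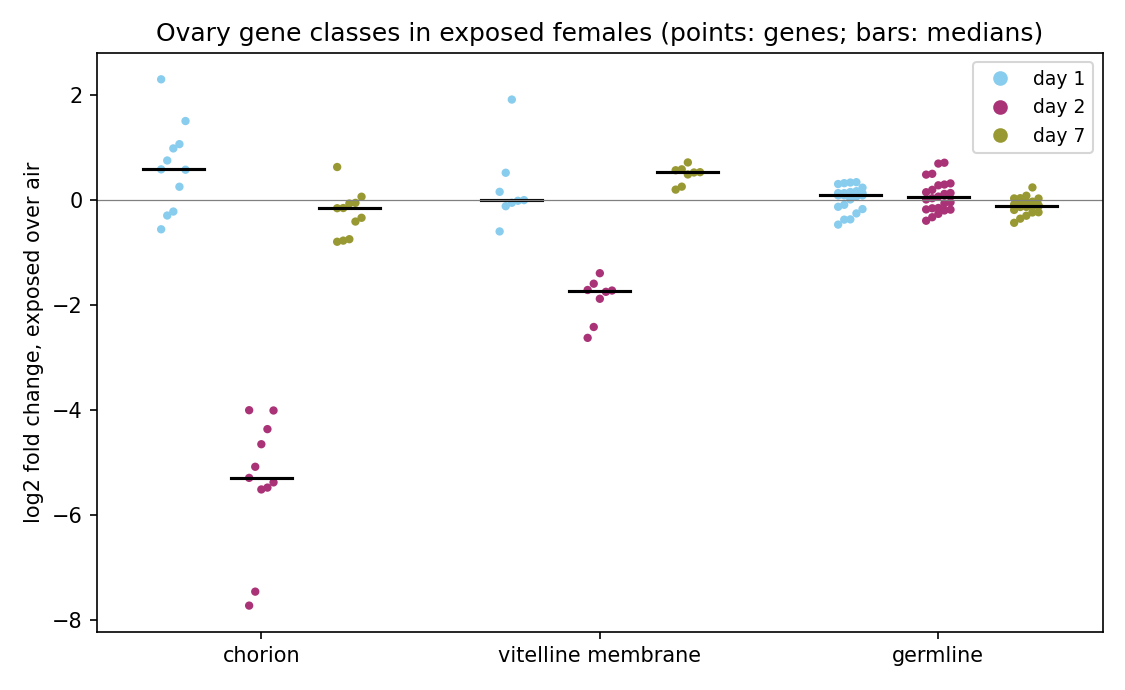
Each point is the log2 fold change of 1 gene in exposed against air females, grouped as chorion, vitelline membrane and germline genes. Lines give the group median for each day shown. On day 2 chorion genes have a median of -5.29, vitelline membrane genes -1.74 and germline genes 0.05.

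Digestive enzymes also fell as a set on day 2 in females, with a median of -1.36 over 41 genes (adjusted p = 2.3e-14; adjusted p = 0.450 with an estimated correlation). None passed over all genes, and 17 fell when adjusted over the list alone. Jon66Ci had -2.79 (adjusted p = 0.0890) and Jon65Ai -2.37 (adjusted p = 0.0949). Once the mixed libraries were left out, Jon65Ai (-3.57, adjusted p = 0.00208) and epsilonTry (-3.92, adjusted p = 0.00693) passed over all genes, and Jon66Ci (-3.34, adjusted p = 0.0683) did not. The mixed library titled female is among these exposed libraries too, and without the mixed libraries the median was -1.99, with 24 lower and 1 higher over the list alone. The list's sum was 14960.3 CPM ± 11684 in air and 6399 CPM ± 5386 in exposed females, or 3399 CPM in the 2 exposed libraries that are not mixed. Air replicate 1 carried the air mean: the air libraries stood at 28448, 8496 and 7937 CPM, and the exposed ones at 12398, 4819 and 1979.6 CPM. Without air replicate 1 the median was -0.47, and the list still passed (adjusted p = 8.1e-05). Among odorant binding and taste genes, Obp19c fell by 4.03 (SE 0.64, adjusted p = 0.00435) and Obp83b by 2.99 (SE 0.58, adjusted p = 0.0211). Without the mixed libraries Obp83b had -3.14 (adjusted p = 0.0527, not past). Of 31 genes, 5 fell when adjusted over the list alone. That list had a median of -0.79 (adjusted p = 0.000378; adjusted p = 0.450 with an estimated correlation). The storage protein gene Lsp2 fell by 2.89 (SE 0.59, adjusted p = 0.0306), while its list, fat body and haemolymph, did not pass (adjusted p = 0.144). Without the mixed libraries Lsp2 had -2.96 (adjusted p = 0.0716, not past).

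Turandot and JAK-STAT genes, several of them stress peptides, rose as a set in females on day 2 (median 0.48, adjusted p = 0.0266; adjusted p = 0.450 with an estimated correlation). Of 10 members, 4 rose when adjusted over the list alone, among them TotA (3.52, adjusted p = 0.148), TotM (3.68, adjusted p = 0.235) and TotC (3.31, adjusted p = 0.268). Neuron genes (0.68; adjusted p = 0.272 with an estimated correlation), photoreceptor genes (0.51; adjusted p = 0.239) and antimicrobial peptides (0.64; adjusted p = 0.629) passed upward at the preset correlation. Mitochondrially encoded genes (-0.59; adjusted p = 0.450 with an estimated correlation), nuclear oxidative phosphorylation genes (-0.35; adjusted p = 0.616) and ribosomal proteins (-0.32; adjusted p = 0.637) passed downward. So did haemocyte genes (-0.46; adjusted p = 0.450 with an estimated correlation) and carboxylesterases and juvenile hormone genes (-0.41; adjusted p = 0.567). Seminal fluid proteins of the male accessory gland had a median of 5.97 (adjusted p = 0.00507; adjusted p = 0.629 with an estimated correlation), with 10 of 11 higher over the list alone. That value moved with the mixed library: without it the median was -1.91 and the list passed downward (adjusted p = 0.000774; adjusted p = 0.450 with an estimated correlation), with none past over the list alone.

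Lists passing numbered 14 in females on day 2, of which 2 held with an estimated correlation, and 19 without the mixed libraries. Those 19 newly included P450s (-0.49), endoplasmic reticulum stress (0.24), apoptosis and DNA damage (0.35), cuticle (-0.44), and fat body genes (-0.52), with adjusted p of 0.595, 0.288, 0.173, 0.173 and 0.568 by an estimated correlation. With the mixed libraries left out 57 genes passed (1 higher, 56 lower), 31 of them shared with the 45. Neither CG14245 (1.55, adjusted p = 0.0768) nor TBC1D5 (1.01, adjusted p = 0.0607) passed then, at folds close to those with all libraries. The directions of the count also moved: 32 rose and 38 fell without exposed replicate 3, 19 and 34 without air replicate 1, 20 and 24 without exposed replicate 2, and 80 and 90 with no filter on low counts. With all 36 libraries in 1 fit 1015 rose and 92 fell. With only the 6 libraries compared no gene passed by edgeR, beside 942 at an unadjusted p below 0.05 in the fit per sex and 124 by DESeq2. Without air replicate 1, the median of nuclear oxidative phosphorylation genes was 0.01 and that of ribosomal proteins 0.07. Other list calls of that day were lost without single libraries, given by adjusted p. These were haemocyte (0.505) and carboxylesterase genes (0.645) without air replicate 1, both (0.188) without exposed replicate 3, and seminal fluid genes (0.0510) without air replicate 2. Antimicrobial peptides (0.347, 0.208 and 0.622) and Turandot genes (0.118, 0.245 and 0.0729) lost theirs without air replicate 2, air replicate 3 and exposed replicate 2.

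For females on day 7, 1 gene fell and none rose among 9893 tested by edgeR, with 324 genes at an unadjusted p below 0.05 and 10 called by DESeq2. Odorant binding protein gene Obp83b (FBgn0010403; 3R, 5976177 to 5976817) went from 6.30 CPM ± 1.46 to 0.272 CPM ± 0.0644, a log2 fold change of -4.49 (SE 0.66, adjusted p = 0.0285, n = 3 per arm). Its neighbour Obp83a had -3.34 and the mitochondrial carrier gene SCaMC -0.65, each with adjusted p = 0.510. On the positive side, transferrin gene Tsf1 had 2.00, CG34227 2.99, CG9512 1.31 and the immune peptide gene Listericin 3.06, all at adjusted p = 0.510. Obp56a had 2.52 (adjusted p = 0.682). Obp83b kept its call without air replicate 3 and lost it without any other single library of that day. All 3 exposed libraries lay beyond all 3 air libraries in 17.3% of genes, where chance gives 10% on average, with a spread that was not tested.

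Gene lists moved upward more than downward in females on day 7: 14 rose and 4 fell at the preset correlation, and none passed with an estimated correlation (lowest adjusted p = 0.106). The 32 antimicrobial peptides had a median of 1.39, with 30 positive, 13 past over the list alone and none past over all genes (adjusted p = 1.4e-21; adjusted p = 0.210 with an estimated correlation). AttA had 3.60, BomBc1 2.32 and CecA1 3.16, each with adjusted p = 1.00. Their sum was 3199.6 CPM ± 845 in air and 7323 CPM ± 2331 in exposed females. Air females stood at 4736 CPM on day 1 and 5900 CPM on day 2, so the rise is measured against the lowest air group of females. Fat body and haemolymph genes had a median of 1.78 and 6 of 10 rose over the list alone (adjusted p = 5.5e-11; adjusted p = 0.106 with an estimated correlation). Npc2e had 2.32 and Lsp2 2.21, both at adjusted p = 1.00. The 41 digestive enzymes had a median of 0.73, with 35 positive and none past over the list alone (adjusted p = 1.2e-10; adjusted p = 0.392 with an estimated correlation). Summed, these enzymes came to 4879 CPM in air and 6948 CPM in exposed females. Air females stood higher on day 1 (8236 CPM) and day 2 (14960 CPM), so this rise too is measured against the lowest air group. Detoxification lists were positive: UDP-glycosyltransferases 0.66 (adjusted p = 0.242 with an estimated correlation), cytochrome P450s 0.35 (adjusted p = 0.413) and glutathione transferases 0.25 (adjusted p = 0.392). Cyp6g1 had 1.37, Cyp9f2 1.23 and GstE9 1.06, each at adjusted p = 1.00.

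The other rising lists on day 7 in females were cuticle proteins (0.47; adjusted p = 0.106 with an estimated correlation), mitochondrially encoded genes (0.45), immune recognition and signalling (0.42), yolk proteins (0.37) and superoxide and peroxide defence (0.30). Haemocyte genes (0.27), lipid synthesis (0.22) and nuclear oxidative phosphorylation genes (0.18) completed them. With an estimated correlation, adjusted p was 0.476 for lipid synthesis, 0.627 for oxidative phosphorylation and 0.392 for the remaining 5 of these. Falling lists were Turandot and JAK-STAT genes (-0.62), neurons (-0.41), photoreceptor genes (-0.27) and heat shock proteins (-0.28). Their adjusted p with an estimated correlation was 0.106 for heat shock proteins and 0.392 for the other 3. Within the heat shock list, lncRNA:Hsromega had -0.73 and was the single member past over the list alone. Calls lost without 1 library, by adjusted p, were those of Turandot genes (air replicate 1, 0.212; exposed replicate 3, 0.0546), photoreceptor genes (air replicate 2, 0.139; exposed replicate 3, 0.0873) and haemocyte genes (exposed replicate 2, 0.0642). Lipid synthesis lost its call without air replicate 1 (0.0729), air replicate 2 (0.104), exposed replicate 1 (0.113) or exposed replicate 2 (0.0594). Yolk proteins lost theirs without air replicate 2 (0.0610), air replicate 3 (0.0585), exposed replicate 2 (0.257) or exposed replicate 3 (0.0546).

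**Figure D3:**
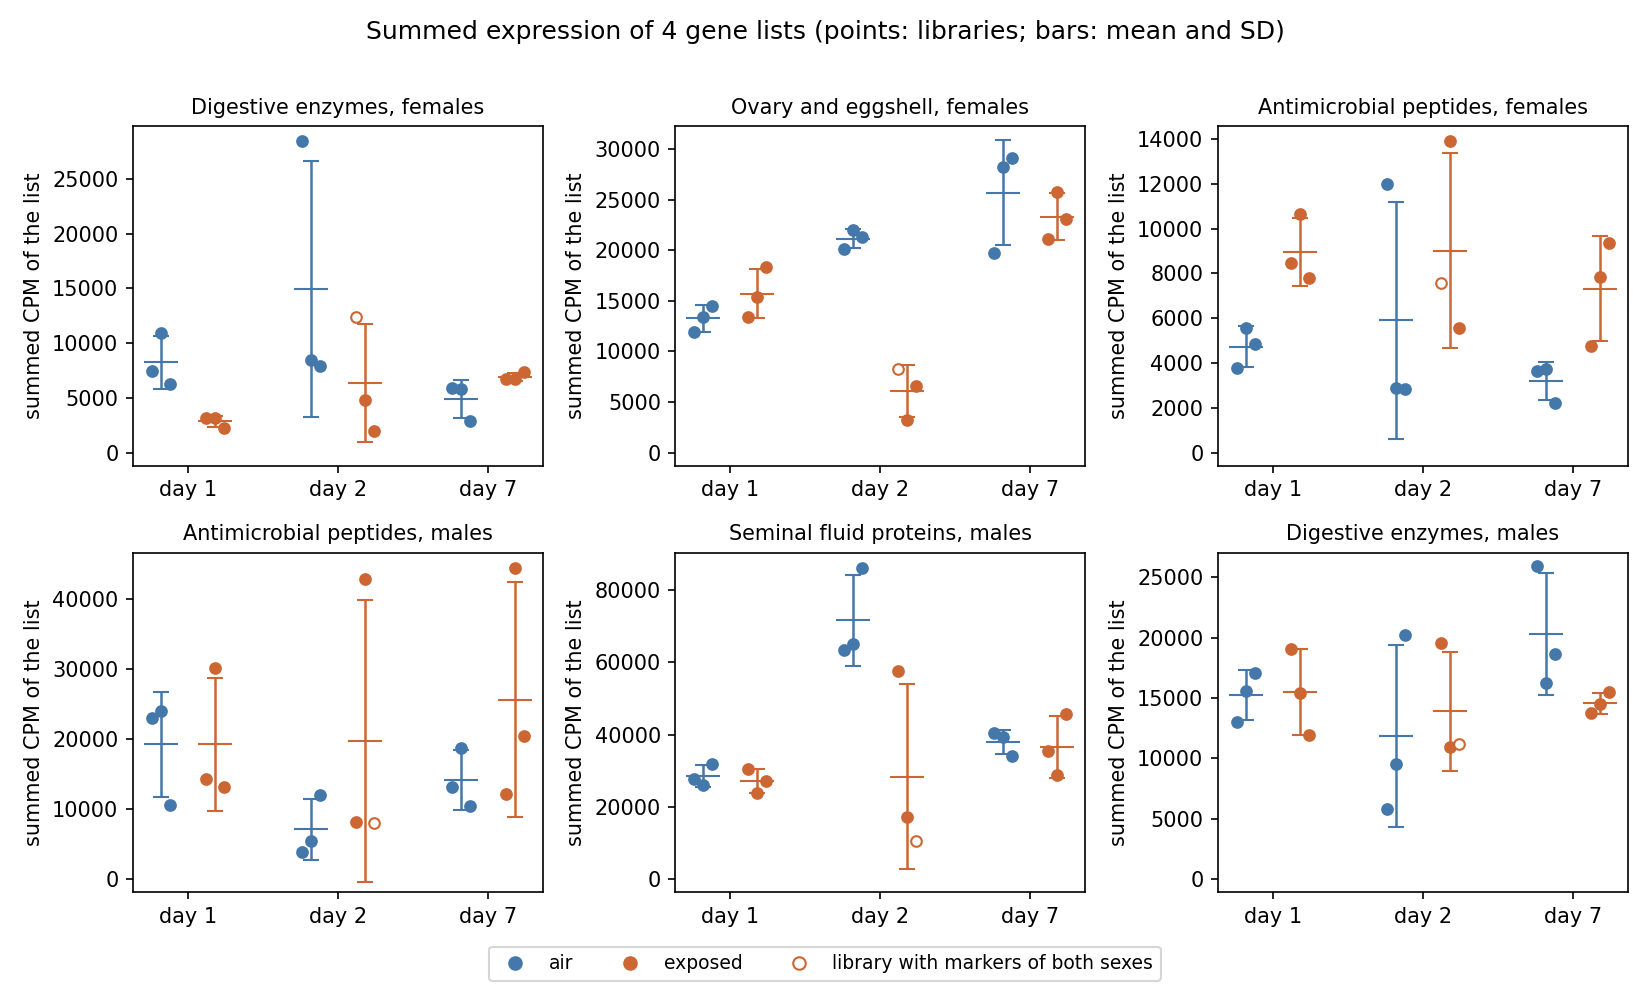
Summed CPM of 4 gene lists is plotted for each of the 36 libraries by day, sex and arm, with group mean and SD. Digestive enzymes of females go from 8236 CPM in air to 2863 CPM on day 1, ovary and eggshell genes from 21119.5 to 6050.2 CPM on day 2, and antimicrobial peptides from 3199.6 to 7323 CPM on day 7.

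In males on day 1, no gene of 12871 passed by edgeR, with 408 at an unadjusted p below 0.05 and none by DESeq2. Positive genes with the smallest p, none past the threshold, included CG12896 (FBgn0033521; 2R, 10426880 to 10427915) and Prx2540-1, peroxiredoxin genes of a tandem cluster. CG12896 had a mean of 19.0 CPM ± 0.520 in air and 207 CPM ± 257 in exposed males, a log2 fold change of 3.45 (SE 0.75, adjusted p = 1.00, n = 3 per arm). Prx2540-1 had 3.03 and Prx2540-2 1.83. These genes are near-identical copies whose reads can be shared, so the value of each is uncertain. The exposed libraries stood at 35.6, 503 and 82.4 CPM of CG12896, against 18.8, 19.6 and 18.6 CPM in air. In females of that day CG12896 stood at 38.6, 133.5 and 27.7 CPM exposed, against 8.80, 15.9 and 11.1 CPM in air. Prx2540-1 stood there at 106.6, 373.5 and 94.4 CPM, against 23.1, 66.1 and 44.4 CPM. For Prx2540-2 the female arms overlapped, with 15.7 CPM in exposed replicate 3 against 19.7 CPM in air replicate 2. Higher values of CG12896 and Prx2540-1 were thus not limited to males. In males the transporter gene MFS12 had 1.71. On the negative side, the hormone gene Ptth had -2.82, cass -0.76, the peptide receptor gene CCHa2-R -4.37 and the copper transporter gene Ctr1A -1.74, all at adjusted p = 1.00.

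In males on day 1, 6 gene lists passed at the preset correlation and none with an estimated one (lowest adjusted p = 0.913). Photoreceptor genes fell as a set, with 21 of 21 negative and a median of -0.56 (adjusted p = 1.7e-08; adjusted p = 0.913 with an estimated correlation). The rhodopsin gene Rh5 had -1.01, inaE -0.72 and ninaA -0.90. Neuron genes had a median of -0.56 with 14 of 14 negative (adjusted p = 5.0e-05), and muscle genes -0.41 with 21 of 24 negative (adjusted p = 1.9e-06); both had adjusted p = 0.913 with an estimated correlation. Syx1A had -0.61 and the titin-like gene sls -0.82. Rising lists were mitochondrially encoded genes (0.46, 12 of 13 positive; adjusted p = 0.913 with an estimated correlation), UDP-glycosyltransferases (0.51; adjusted p = 0.913) and ribosomal proteins (0.23, 73 of 73 positive; adjusted p = 0.949). No member of these 6 lists passed over the list alone. Within the glutathione and thioredoxin system 2 of 24 rose over the list alone, while the list did not pass (adjusted p = 0.227). List calls numbered 10 without exposed replicate 3. UDP-glycosyltransferases lost theirs without air replicate 2 (adjusted p = 0.190) and muscle genes without air replicate 1 (adjusted p = 0.0540).

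For males on day 2, no gene of 12871 passed by edgeR (smallest adjusted p = 0.0697), although 2811 had an unadjusted p below 0.05, 2129 of them positive. DESeq2 called 865 genes, 708 higher and 157 lower. Among positive genes with the smallest p, the yolk receptor gene yl had 10.17 (adjusted p = 0.0782), from 0.112 CPM ± 0.108 in air to 146 CPM ± 249 in exposed males. Pxt (10.28), PolE2 (8.76), CG43134 (4.73) and CG12499 (3.25) had the same adjusted p. Leaving out the mixed libraries took these 5 to 4.06, 3.93, 4.58, 1.32 and 1.47. Lower values, also short of the threshold, were those of snoRNA:Psi18S-531 (-2.89, adjusted p = 0.0697) and the alcohol dehydrogenase gene Adh (-2.22, SE 0.42, adjusted p = 0.0782). The former lies inside the ribosomal protein gene RpL22, and the strand used in counting is not stated, so its value is uncertain. tRNA:Ala-TGC-1-1 (-5.00), lncRNA:CR44761 (-1.55) and lncRNA:let7C (-1.70) had adjusted p = 0.0782. Without the mixed libraries no gene passed either, with 925 at an unadjusted p below 0.05, and the smallest adjusted p values were those of Cyp4e3 (4.55), AttC (6.43) and Mtk (6.79), each 0.0762.

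Seminal fluid proteins fell as a set in males on day 2: 26 of 26 were negative with a median of -1.22, and 22 fell when adjusted over the list alone (adjusted p = 7.3e-24; adjusted p = 0.689 with an estimated correlation). Dup99B, a ductus peptide gene, had -1.51 (SE 0.41, adjusted p = 0.0847) and Acp54A1 -1.52 (adjusted p = 0.0886). Their sum was 71536 CPM ± 12637.5 in air, and 57545, 17115 and 10515 CPM in the 3 exposed libraries, the last of them mixed. Air males stood at 28553 CPM on day 1 and 37875 CPM on day 7, so the fall is measured against the highest air group of males. The median was -0.86 without the mixed libraries, and 15 fell over the list alone (adjusted p = 0.382 with an estimated correlation). Antimicrobial peptides had a median of 1.35, with 31 of 33 positive, 12 higher and 1 lower over the list alone (adjusted p = 1.7e-05; adjusted p = 0.689 with an estimated correlation). AttC had 5.86 and Mtk 6.21, both at adjusted p = 0.0782. Exposed replicate 2 carried this list: without it the median was 0.35 and the list did not pass (adjusted p = 0.257). The median was 1.63 without the mixed libraries, and 20 rose over the list alone. Summed, these peptides came to 7113 CPM ± 4295 in air males and 19733 CPM ± 20088 in exposed males on day 2. Air males stood at 19262 CPM on day 1 and 14171 CPM on day 7, so the rise is measured against the lowest air group of males.

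Several list calls in males on day 2 moved with the mixed library titled male. Yolk proteins (7.04), ovary and eggshell genes (3.35, 18 higher over the list alone) and apoptosis and DNA damage genes (1.64, 9 higher over the list alone) passed upward. Each had adjusted p = 0.689 with an estimated correlation. Among the latter, RnrS and RnrL, which encode ribonucleotide reductase, had 4.75 and 5.29. None of these 3 lists passed without the mixed libraries, and none had a member past over the list alone. Proteasome genes (0.46; adjusted p = 0.785 with an estimated correlation) and ribosomal proteins (0.36; adjusted p = 0.791) were positive with it and had medians of -0.03 and -0.06 without. Testis genes (-0.40; adjusted p = 0.713), muscle (-0.33; adjusted p = 0.713), photoreceptor (-0.24; adjusted p = 0.713), neurons (-0.55; adjusted p = 0.689), cuticle proteins (-0.42; adjusted p = 0.689), odorant binding genes (-0.65; adjusted p = 0.689) and carboxylesterases (-0.32; adjusted p = 0.689) fell with it and did not pass without it. Those p values are with an estimated correlation. Mitochondrially encoded genes (0.42, then 0.64), nuclear oxidative phosphorylation genes (-0.21, then -0.12) and clock genes (-0.41, then -0.32) passed with and without it. With an estimated correlation, their adjusted p was 0.713, 0.689 and 0.689. Calls lost without 1 library that is not mixed, by adjusted p, were those of mitochondrial genes without air replicate 1 (0.332), exposed replicate 1 (0.0531) or exposed replicate 2 (0.273). Without air replicate 1 ribosomal (0.0595) and testis genes (0.0563) lost theirs, and without air replicate 2 photoreceptor (0.0590) and carboxylesterase genes (0.0502). Without air replicate 3 cuticle (0.116), clock (0.0616), odorant binding (0.261) and carboxylesterase genes (0.337) did. In all, 17 lists passed and none did with an estimated correlation. Of the 10 passing without the mixed libraries, 5 were among the 17. The others were glutathione transferases (0.20), superoxide defence (0.41), starvation and insulin response (0.39), glycolysis (-0.26) and lipid synthesis (-0.33), each at adjusted p = 0.719 with an estimated correlation. The gene count was 2490 without exposed replicate 1, 892 without exposed replicate 2 and 1 without air replicate 1, and in the first 2 of these the mixed library makes up 1 of 2 exposed libraries.

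In males on day 7, no gene of 12871 passed by edgeR, with 120 at an unadjusted p below 0.05 and none by DESeq2. CG13300 had a log2 fold change of 3.58 (2.56 CPM ± 1.26 to 31.1 CPM ± 47.4, SE 0.89, n = 3 per arm), CG30377 3.53, the engrailed-family gene inv 1.95 and the acetylcholine receptor gene nAChRalpha3 2.00. Negative values were those of CG1983 (-1.02), the troponin gene TpnC4 (-2.25) and CG3348 (-0.84), and all these genes had adjusted p = 1.00. Hr4 had 3.95 and -0.46 without exposed replicate 2. The noncoding RNA lncRNA:cherub had -5.24 and 0.42 without air replicate 1. Groups did not overlap in 8.60% of genes, where chance gives 10% on average, with a spread that was not tested.

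In males on day 7, 5 lists passed at the preset correlation and none with an estimated one, where each had adjusted p = 0.936. Antimicrobial peptides rose with a median of 0.90 and 28 of 33 positive (adjusted p = 1.7e-08), but had a median of -0.02 without exposed replicate 2. That library was the shallowest of the 36 (4681333 counts) and had the highest share of mitochondrial messenger RNA (5.86%). Among the 17 male libraries that are not mixed it had the lowest roX1 (847 CPM) and the highest Yp1 (176 CPM). BomBc1 had 3.02 and CecB 3.43, both at adjusted p = 1.00. Ovary and eggshell genes (0.60, adjusted p = 0.00314) and mitochondrially encoded genes (0.22, adjusted p = 0.0451) passed upward. Digestive enzymes (-0.22, 31 of 42 negative, adjusted p = 0.000202) and starvation and insulin response genes (-0.18, adjusted p = 0.00717) passed downward. None of their members passed over the list alone. The ovary and eggshell list lost its call without air replicate 2, exposed replicate 1 or exposed replicate 2 (medians 0.45, -0.15 and 0.61), and the mitochondrial list turned to -0.09 without air replicate 1 and missed the threshold without the mixed libraries (adjusted p = 0.0659). The mitochondrial list also lost its call without exposed replicate 2 (adjusted p = 0.570) or 3 (0.132), digestive enzymes without air replicate 1 (0.166) or exposed replicate 1 (0.0786), and starvation genes without exposed replicate 1 (0.140). The number of lists was 3 without air replicate 1, 3 without exposed replicate 1 and 9 without air replicate 3.

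Whether the effect differed between sexes was tested directly in all 36 libraries over 13241 genes. On day 1 the effect on CG14963 was 2.13 in males and -6.78 in females, a difference of -8.91 (SE 1.45, adjusted p = 0.0155). In females it rests on 148 counts against 1, a ratio of 165 with a 95% counting interval of 29.2 to 6572. For Alp9 the effects were -0.21 in males and -8.96 in females (difference -8.75, SE 1.57, adjusted p = 0.0366). These were the 2 genes past the threshold on day 1. On day 2, 1619 genes differed, 1027 with the more positive effect in females and 592 with the more negative. The eggshell gene yellow-g led the second set, with 0.46 in males and -7.67 in females (difference -8.12, SE 1.01, adjusted p = 0.000111). Cp36 differed by -8.81 (adjusted p = 0.00781), or by -7.47 (adjusted p = 0.0327) without the mixed libraries. Seminal fluid gene Sfp26Ad led the first, with a difference of 8.02 (adjusted p = 0.0157) that was 0.69 (adjusted p = 0.915) without the mixed libraries. Without the mixed libraries 11 genes differed on day 2, 8 of them shared with the 1619, and 7 on day 1, of which 2 were shared. The ovary and eggshell list differed by a median of -7.51 on day 2 (adjusted p = 0.139 with an estimated correlation), and of -3.67 without them (adjusted p = 0.0378). Its sum on day 2 was 307 CPM in air males and 21119.5 CPM in air females. With so little male expression, differences in these genes say little on how males responded. On day 7 no gene differed by edgeR, with 176 at an unadjusted p below 0.05 and 37 by DESeq2.

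Both sex-difference counts depended on single libraries. On day 1 the 2 genes became 0 without male air replicate 2 or 3, male exposed replicate 2 or female exposed replicate 3. They became 1 without female air replicate 1 or male exposed replicate 1 or 3, and 4 without female air replicate 2 or female exposed replicate 2. On day 2 the 1619 genes became 2 without the mixed male library, 63 without the mixed female library, 63 without female air replicate 2 and 59 without female air replicate 3. The count was 564 without male air replicate 1, 1033 without male air replicate 2 and 3218 without male exposed replicate 1. Directions moved too: 823 were more positive in females and 316 more negative with DESeq2 size factors, 921 and 225 with replicate number as a block, 1023 and 1120 without male exposed replicate 2, and 0 and 11 without the mixed libraries.

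The effect changed over the 3 days for 44 genes in females. The list was led by yellow-g, with log2 fold changes of 1.06, -7.72 and 0.06 on days 1, 2 and 7 (adjusted p = 6.8e-05). Cp7Fb had 1.51, -5.08 and -0.07 (adjusted p = 0.000589), and CG32645 had 1.63, -2.46 and -0.02 (adjusted p = 0.000719). CG4009, CG14834, PH4alphaPV, CG13114, CG15570, yellow-g2 and Cad74A followed, each with its lowest value on day 2. With the mixed libraries left out 86 genes changed, 42 of them shared, and these included Jon25Bi (-5.76, -6.68 and 3.09) and Alp9 (-9.01, -3.92 and 1.75). In males no gene changed over the days by edgeR, with 985 at an unadjusted p below 0.05 and 2 by DESeq2. On simulated data this test recovered 0 of 66 changes of 4-fold in males and 33 of 66 in females, so the 0 in males is no contrast with females. The male count was 214 without day 2 exposed replicate 1, which leaves the mixed library as 1 of 2 exposed libraries of day 2.

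The female count of 44 was moved by many single libraries. On day 1 it was 23, 22 and 28 without air replicate 1, 2 and 3, and 25 and 21 without exposed replicate 2 and 3. On day 2 it was 150 without air replicate 1, 86 without the mixed library and 68 without exposed replicate 3. On day 7 it was 18 and 24 without air replicate 2 and 3, and 27, 19 and 18 without exposed replicate 1, 2 and 3.

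Over the 6 comparisons of exposure, 70 genes passed in at least 1, and no gene passed in the same direction in more than 2. The genes lower in females on day 1 and on day 2 shared none (expected 0.0739). Once the mixed libraries were left out they shared Alp9, CG12374, Jon25Bi and Obp19d, against 0.210 expected. Obp83b fell on both day 2 and day 7 (expected 0.00435). With the mixed libraries left out those days shared none, and Obp83b fell on day 1 and day 7 (expected 0.00375). Across 7181 genes, female fold changes on day 1 and day 7 had a Pearson correlation of -0.410 and a Spearman correlation of -0.396. The Pearson value was 0.203 for days 1 and 2 (0.327 without the mixed libraries) and -0.186 for days 2 and 7 (-0.181). Genes are not independent replicates, so no p-value is given for overlaps or correlations. Of the 37 gene lists, 6 passed in none of the 6 comparisons: glutathione and thioredoxin system, endoplasmic reticulum stress response, JNK pathway and wounding, glycolysis, hypoxia response and trachea. With the mixed libraries left out, 2 of these passed on day 2, glycolysis in males (-0.26) and endoplasmic reticulum stress in females (0.24). Neither of the 2 passed with an estimated correlation.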

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

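The tests of mixed libraries, of male RNA in the exposed arm, of a starvation-like response and of other splits were chosen only after the results were seen; those of less midgut, less ovary and late follicle stages were set before their values were seen, but the rule labelling the last was narrowed afterwards to what had been set.

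By a test of the difference itself, with the mixed libraries kept, the effect of exposure differed between sexes for 2 genes on day 1 and 1619 on day 2. On day 1 these were CG14963 (female minus male -8.91) and Alp9 (-8.75). Of the 40 splits tested on that day, 7 gave as many genes, with a highest other count of 37, so chance is not excluded. On day 2 the genes led by p were Sfp26Ad (8.02), BG642167 (8.25), ppk22 (8.59), lncRNA:CR43239 (8.95) and lncRNA:CR44546 (10.14) upward. Downward they were yellow-g (-8.12), CG14834 (-4.63), CG13114 (-9.72), CG4009 (-11.30) and Cp36 (-8.81). There 8 of 40 splits gave as many genes, with a highest other count of 2833. Every split kept both mixed libraries and could move them between arms. Chance is therefore not excluded, and the splits cannot tell it apart from the placement of those libraries. Leaving out the mixed male library alone took the count from 1619 to 2. Without the mixed libraries 11 genes differed, and the 5 upward genes had adjusted p of 0.915, 0.893, 0.165, 0.982 and 0.941. Downward, CG4009 also lost its call (-9.70, adjusted p = 0.279), and the other 4 passed. On day 7 there were 0 genes by edgeR, 176 at an unadjusted p below 0.05 and 37 by DESeq2. All 40 splits give as many as 0 by definition, which decides nothing.

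The effect also differed between days for 44 genes in females. Of 100 splits, 1 gave as many, the real one, and the highest other count was 18. That argues against a chance split of these samples as the source of the count. The splits were chosen after the count was seen and do not cover its dependence on single libraries (18 to 150 genes). In males 0 genes differed by edgeR, 985 had an unadjusted p below 0.05 and DESeq2 called 2. The highest other count was 2. Against a real count of 0 all 100 splits give as many by definition, which decides nothing.

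The first pattern weighed is that of both sexes' markers in 2 exposed libraries of day 2. An exchange of the labels is argued against by the lower roX1 value of the pair, 209.8 CPM, which lies outside the range of either sex. Entry of 1 library under both labels is argued against by a chi-square per degree of freedom of 29.99 between them. The 2 were still alike: that value lies below the replicate median of 50.7. Their log2 CPM correlated at 0.983 with each other, against 0.871 to 0.915 with the other libraries of their own groups. Male and female RNA combined remains a candidate explanation: testis genes in the library titled female stood at a median ratio of 0.211 to the day 2 exposed males, with quartiles of 0.190 and 0.240 over 22 genes. In the library titled male that ratio was 0.192, roX1 stood at 0.147 of those males and dhd at 0.838 of the day 2 exposed females. Seminal fluid genes had median ratios of 0.268 in the library titled male and 0.243 in the one titled female. By roX1, dhd, testis and seminal fluid genes, the library titled male thus lay nearer the females. It was still 1 of the 3 exposed libraries of males in the main fit. Ovary and eggshell ratios in the library titled female spread more, with quartiles of 0.511 and 2.50, so they give no single share. Whether flies, RNA or libraries were combined was not tested, and no biological explanation was tested.

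The second pattern is that of lower digestive enzymes in exposed females. On day 2, a loss of midgut tissue as large as the fall of the enzymes is argued against by midgut markers that are not enzymes. Their median was -0.48, with quartiles of -0.66 and -0.06, against -1.36 for the enzymes. Of 13 markers 10 were lower and 3 higher, or 11 and 2 without the mixed libraries, so a smaller loss of midgut is not excluded. Male RNA is argued against by an enzyme median of -1.99 without the mixed libraries. After the values were seen, the test of midgut tissue was repeated without each library of that day. The markers still argued against a loss of that size without air replicate 1 (0.045 against -0.47), exposed replicate 1 (-0.62 against -1.99) or exposed replicate 3 (-0.048 against -1.001). Without air replicate 2 (-0.58 against -1.57) or 3 (-0.71 against -1.62) they decided nothing, and without exposed replicate 2 (-0.60 against -1.15) they went with less midgut tissue, so the argument depends on single libraries. On day 1 the midgut markers had a median of -0.83 (quartiles -2.10 and -0.48) against -1.78, so less midgut tissue cannot be told apart from lower enzyme expression. A starvation-like response stays open, since its list missed the threshold (adjusted p = 0.664), which decides nothing. An effect of exposure on enzyme expression may be part of the pattern and was not tested apart from these.

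The third pattern is that of lower eggshell genes in exposed females on day 2. Less ovary tissue is argued against by germline markers, with a median of 0.050 (quartiles -0.16 and 0.28, 24 genes) against -4.01 for 19 eggshell genes, and male RNA by the 29 ovary and eggshell genes, with a median of -1.75 and of -2.58 without the mixed libraries. A loss limited to late follicle stages cannot be told apart from a loss over all stages. Vitelline membrane genes, which are made earlier, had a median of -1.74 with none of the 8 past the threshold, lower than the bound of -1 set for a late loss, while chorion genes stood lower still at -5.29. An effect of exposure on eggshell expression may be part of the pattern and was not tested apart from these.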

How the results depend on the processing

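Leaving out the mixed libraries, and leave-one-out for lists, were chosen only after the data were seen. The cause was not tested for any change below, except where the mixed libraries are named.

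Without the mixed libraries, genes numbered 54 in females on day 1, 86 for the change over days in females, 7 and 11 for the sex difference on days 1 and 2, and lists 10 in males on day 2. Reversed without them were proteasome (-0.034) and ribosomal genes (-0.058) in males on day 2, seminal fluid (-1.91), Acp53C14a (-1.36), SP (-1.75) and Acp98AB (-1.33) in females on day 2, and lncRNA:CR43239 (-0.64) for the sex difference. The medians of photoreceptor (0.089) and testis genes (0.036) in males on day 2 also changed sign, and neither list passed.

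With DESeq2 the counts were 865 (day 2 males), 273, 124 and 10 (females on days 1, 2 and 7), 2 and 245 (change over days in males and females), and 125 and 37 (sex difference on days 1 and 7). With no filter they were 215 in males on day 2, 119, 170 and 4 in females, and 161 over days in females. The stricter filter gave 10 in females on day 1 (7 higher, 3 lower). All 36 libraries in 1 fit gave 1419 in males on day 2 and 74, 1107 (1015 higher, 92 lower) and 0 in females, and only the 6 libraries compared gave 185, 0 and 13 in females. The 0 on day 7 from all 36 libraries and the 0 on day 2 from 6 are edgeR counts, beside 324 and 942 genes at an unadjusted p below 0.05 in the fit per sex. The threshold of the series text, which is not adjusted, gave 373, 2752 and 119 in males and 953, 701 and 267 in females. DESeq2 size factors moved the median of all genes by at most 0.021.

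With replicate number as a block, counts were 1 in males on day 2, 141 over days in females and 1 for the sex difference on day 1. In females they were 124 on day 1 (17 higher, 107 lower) and 88 on day 2 (4 higher, 84 lower). Taken over all days the numbers do not pair arms: 4 of 18 correlations between like numbers were above 0.1 (-0.139 to 0.433). All 4 were on day 2, for replicates 1 and 3 of males (0.220 and 0.164) and of females (0.358 and 0.433). In each of these the best match in the other arm had the same number. Replicate 2 of that day did not match its number (0.009 in males and -0.118 in females). Some pairing on day 2 is therefore not excluded.

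With an estimated correlation, and with fry, 0 lists passed in every comparison except females on day 2, where 2 did.

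Leaving out 1 library at a time gave 0 to 2490 genes in males on day 2, 0 to 34, 39 to 70 and 0 to 1 in females on days 1, 2 and 7, 0 to 214 and 18 to 150 over days in males and females, and 0 to 4 and 2 to 3218 for the sex difference on days 1 and 2. Lists numbered 6 to 10, 10 to 20 and 3 to 9 in males and 8 to 16 in females on day 1. The extremes in males on day 2 and over days came without exposed replicate 1 (2490 and 214). Medians that turned ranged from -0.034 to 0.66 (proteasome) and -0.058 to 0.58 (ribosomal) in males on day 2, and from -0.089 to 0.38 (mitochondrial) in males on day 7. In females on day 2 they ranged from -0.49 to 0.0080 (oxidative phosphorylation), -0.50 to 0.070 (ribosomal) and -1.91 to 7.31 (seminal fluid). Medians of lists no longer past the threshold also changed sign: antimicrobial peptides (-0.018) and ovary and eggshell genes (-0.15) in males on day 7, testis genes (0.00045 without air replicate 1) in males on day 2, Turandot genes (-0.047) in females on day 1 and haemocyte genes (0.031) in females on day 2. Genes that turned were Hr4 (-0.46 to 4.53), lncRNA:cherub (-6.12 to 0.42), BomS1 (-0.23 to 2.65) and COX1 (-0.084 to 0.68) in males on day 7, and TotA (-0.13 to 2.14) in females on day 1. Acp53C14a (-1.36 to 7.40), SP (-1.75 to 6.77), Acp98AB (-1.33 to 7.37) and lncRNA:CR43239 (-0.29 to 10.11) turned without the mixed female library.

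Of named genes under the other settings, 2193 values kept direction and side of the threshold, 235 newly passed, 48 no longer passed and 4 reversed. Most of the 2193 are of genes not past the threshold in the main fit. Of genes past it, 17 kept and 17 lost their call with only the 6 libraries compared. Without the mixed libraries 45 kept it, 11 lost it and 1 reversed. Kept and lost were 28 and 7 with all 36 libraries, 49 and 7 with the stricter filter, 53 and 4 with the replicate block, and 55 and 2 with DESeq2 size factors. With DESeq2, and with no filter, 57 kept it. At the lowest depth, 3 counts are 0.641 CPM, so genes below that level were not measurable there.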

Other observations

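Comparisons of 3 against 3 libraries allow 10 splits, too few for a share under 0.05, and all these split tests were chosen after the results were seen. Counts of genes in the real split and the highest other split were 26 and 0 in females on day 1, 45 and 135 on day 2, and 1 and 0 on day 7. As many genes came from 1, 2 and 1 of the 10 splits. The 135 genes in females on day 2 came from grouping air replicate 1 with exposed replicates 1 and 2, several times the real count, which points to a structure of the samples. In males the real count was 0 by edgeR on each day, with 408, 2811 and 120 genes at an unadjusted p below 0.05 and 0, 865 and 0 by DESeq2. The highest other counts were 0, 6 and 0. Against a real count of 0 every split gives as many, so these splits decide nothing.

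For gene lists, the real and highest other numbers were 6 and 10, 17 and 24, and 5 and 10 in males on days 1, 2 and 7, and 16 and 7, 14 and 19, and 18 and 16 in females. As many lists came from 3, 4 and 10 of the 10 splits in males and from 1, 8 and 1 in females.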
